A study of Mus musculus with 16 samples.

How the data were processed

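Rod photoreceptors were isolated by flow sorting of green fluorescent protein from retinas of C57BL/6J mice in which the promoter of Nrl, the transcription factor that specifies rods, drives the reporter. Per the labels' protocols, resorting showed a purity above 98%, libraries were made from 4 ng of RNA with a stranded total RNA kit for small inputs and 13 PCR cycles, and paired reads of 125 bases were read on a HiSeq 2500 instrument. The 16 libraries fall into 4 ages (3, 12, 18 and 24 months, written 3M, 12M, 18M and 24M) with 4 libraries each, which the design text calls biological replicates. Whether a replicate is 1 mouse or a pool of mice is not given in the sources used here. The protocol also speaks of mice without Nrl, but each of the 16 libraries carries the label of the reporter strain.

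The authors deposited a table of estimated counts per transcript for the 16 libraries, which are not whole for many transcripts. The submitters' processing notes name kallisto 0.42.5, edgeR 3.13.9, limma 3.32.2 and the genome build GRCm38.p4, with no role or order. A second table from the authors holds a signal per gene in CPM (counts scaled to a common library total), whose libraries sum to 936588 to 1055611, so it was scaled by an effective library size. Another table deposited by the authors holds normalized CPM signal of 11826 genes in 13 libraries, in which each library is the gene CPM times 1 constant. 12M replicate 4, 18M replicate 3 and 24M replicate 3 are not in that table, and the reason is not given in the sources used here. The authors' deposited table of comparisons gives, per the file headers, log2 differences of each later age from 3M, a mean log2 expression, an F statistic as a score, and its p-value and adjusted p-value. How transcripts were summed to genes in the authors' tables, the annotation behind the counting and its strand setting are not given in the sources used here.

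From the estimated counts, 111896 of 113468 transcripts were matched to genes of the GENCODE annotation of GRCm38 by transcript identifier, and the unmatched ones held 0.73% to 1.08% of the counts of a library. Estimated counts were summed to 45038 genes and rounded to whole numbers. Total estimated counts were 20579144 to 28791777 per library. Genes with at least 5 CPM in at least 4 libraries were tested, which left 12177, of which 10303 are protein-coding. Intervals of counts cover counting error only, since reads after PCR without molecular identifiers are not independent molecules. No 2 libraries agreed within sampling noise, since the lowest chi-square per degree of freedom between any pair was 9.

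Tests used the quasi-likelihood fit of edgeR 4.0.16 in R 4.3.3, with TMM factors and a mean per age over all 16 libraries. Each later age was compared with 3M, 18M with 12M, and 24M with 18M. An F-test asked for any difference among the 4 ages, and a second fit took age in months as a linear term. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and genes under 0.05 are called. The common biological coefficient of variation was 0.169. CPM values in the text use the TMM factors and are given as mean ± SD over the 4 libraries of an age.

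Before the data were examined, 50 gene lists of pathways, cell type markers and sex-linked genes were fixed, with 1280 entries of which 3 were not found in the count table. The 40 lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. An estimated correlation and the rotation test fry were run beside it, with Benjamini-Hochberg adjustment over the lists. The rule for named genes took protein-coding genes with a mean of at least 5 CPM, an adjusted p under 0.05 and no overlap between the libraries of both ages. It named the 12 largest rises and 12 largest falls at 24M against 3M, and 6 of each in the other comparisons. It also named the 6 rising and 6 falling genes with the smallest p for the linear term, up to 4 members with the smallest p of each list described, and a fixed set of rod, cone, glial and DNA methylation genes. Gm28876, Edn2, Stat3, Mmp2, Sept4 and Siglech fall outside the rule and were chosen after their values were seen. Some genes that the rule or the fixed set names are not reported here.

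Alternatives fixed at the same time were DESeq2 1.42.0, limma voom with and without sample quality weights, DESeq2 size factors in place of TMM, a minimum of 1 CPM, no filter, limma on the authors' normalized CPM with pseudocounts of 0.5 and 2, fits of the compared ages alone, a block for the replicate number, and each library left out in turn. Alternatives chosen after seeing the data were the 13 libraries of the authors' normalized table, the transcript-length slope and the GC slope of each library as a covariate, and the length slope in those 13 libraries. A slope is the change in a library's log2 CPM, less the mean over libraries, per doubling of transcript length or per 10 percentage points of GC content, over 10296 protein-coding genes. Correlations across libraries have permutation p-values from 100000 permutations. Single values of 2 ages were compared with two-sided exact permutation tests, for which 4 libraries against 4 allow no p below 0.0286. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining computing.

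The tests were tried on simulated counts of the 12177 genes, in which 50 genes were changed at 24M at each of 4 fold sizes. For 24M against 3M, edgeR called 30 of 50 genes changed 1.5-fold, 48 of 50 changed 2-fold, 49 of 50 changed 3-fold and 49 of 50 changed 4-fold, with 5 false calls among 188. In the same data voom made 6 false calls among 188 and DESeq2 27 among 220. A list raised in the simulation had a camera p of 5.35e-23 and an unchanged list one of 0.803. The simulated genes were drawn independently, whereas the estimated correlation in the real data was 0.802 for the ribosomal protein list. This trial therefore does not show how camera with the preset correlation, or the rate of false calls, holds in the real libraries.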

Results

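RNA of sorted mouse rod photoreceptors, the dim-light sensory neurons of the retina, was sequenced at 3, 12, 18 and 24 months of age, with 4 libraries per age and 20579144 to 28791777 estimated counts per library. The design asks which transcripts of rods change as the animal ages. Gnat1, the rod transducin alpha subunit, stood at 5230 ± 466 CPM at 3M and 4190 ± 884 at 24M (SD, n = 4). Summed CPM of 16 cone markers was 187 ± 35.7 at 3M and 208 ± 15.8 at 24M, of 16 bipolar cell markers 290 ± 22.8 and 286 ± 24.4, of 21 endothelial cell and pericyte markers 485 ± 20.1 and 474 ± 87.5, of 9 astrocyte markers 444 ± 17.2 and 362 ± 29.1, and of 24 Müller glia markers 379 ± 83.9 and 484 ± 55 (SD, n = 4). Only 4 endothelial and 4 astrocyte markers passed the expression filter, so few genes carry those sums. The astrocyte list also holds Aldoc, a member of the glycolysis list, so its sum is not a measure of astrocytes alone.

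The libraries were spread along 2 main axes. The first principal component held 53% of the variance of log2 CPM. Its means were highest at 3M but not ordered by age, at 13.3 ± 15.2 for 3M, -6.54 ± 31.7 for 12M, -8.90 ± 16.6 for 18M and 2.17 ± 28.8 for 24M (SD, n = 4). No test of this component against age was run. Among 4 library measures compared with it by permutation tests over 16 libraries, it tracked the slope of expression on transcript length (Pearson r = -0.974, permutation p = 1e-05; rank correlation -0.962, p = 1e-05) and on GC content (r = 0.977, p = 1e-05; rank correlation 0.944, p = 1e-05), where 1e-05 is the smallest p the permutations can give. The share of small noncoding RNA also tracked it (r = 0.866, permutation p = 1e-05; rank correlation 0.821, p = 0.00017) and the total of estimated counts did not pass the test (r = -0.19, permutation p = 0.48; rank correlation -0.179, p = 0.51). Benjamini-Hochberg values of r were 1.3e-05 for the first 3 measures and 0.48 for the total, and those of the rank correlation 2e-05, 2e-05, 0.00023 and 0.51. Without the 2 libraries farthest from the median of each measure, r was -0.954, 0.974, 0.819 and 0.028. Both slopes and the first component were computed from the same log2 CPM values, so a large r is partly built in. Their p-values do not compare independent measures. The labels give no batch within which to repeat these relations. Mean length slopes were -0.047 ± 0.025 at 3M, 0.018 ± 0.101 at 12M, 0.021 ± 0.053 at 18M and 0.008 ± 0.088 at 24M (SD, n = 4). The second component held 14.1% of the variance and had means ordered by age, 17.3 ± 3.76, 1.06 ± 3.00, -4.64 ± 2.71 and -13.7 ± 4.71 from 3M to 24M (SD, n = 4).

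**Figure D1:**
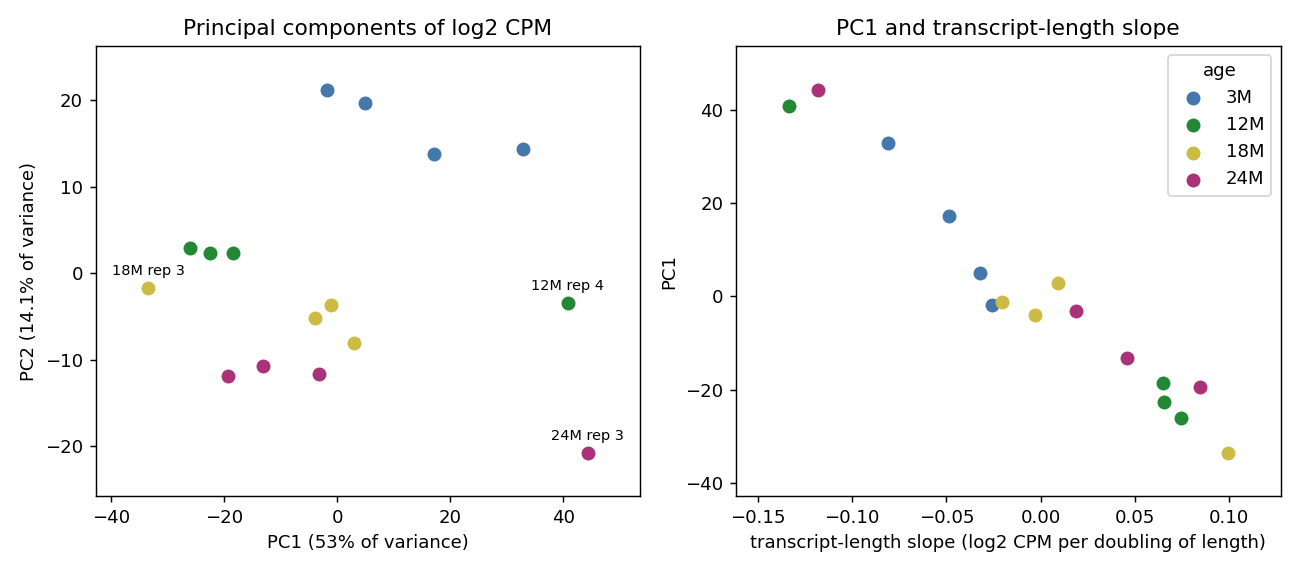
The left panel plots the first against the second principal component of log2 CPM (53% and 14.1% of the variance), and the right panel the first component against the transcript-length slope (log2 CPM per doubling of length), with 1 point per library and colours for the 4 ages. Along the second component 3M and 24M lie apart from the other ages and 12M (-3.42 to 2.96) overlaps 18M (-8.09 to -1.68), while 12M replicate 4 and 24M replicate 3 lie at the far end of the first at 40.76 and 44.28.

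The comparison of 24M with 3M spans the whole age range. The antigen presentation genes Tap2, Erap1, H2-K1 and H2-Q4 and the type IV collagen genes Col4a3 and Col4a4 were higher in the sorted cells at 24M. The photoreceptor repressor Prdm1 and the transducin partner Pdc were lower. Calcr, the calcitonin receptor, rose 21.5-fold from 0.693 ± 0.147 to 15.1 ± 5.6 CPM (SD, n = 4). Prdm1, a zinc finger repressor that sets rod against bipolar fate in the developing retina, was 4.07-fold lower at 24M, at 6.31 ± 1.77 CPM against 25.8 ± 1.09 (SD, n = 4).

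In all, 323 genes were higher and 195 lower at 24M by the edgeR test, 105 and 41 of them at least 2-fold. Of the 518 called genes, 506 had no overlap between the 4 libraries of each age, against 1291 of all 12177 genes (10.6%), where chance gives 2.86%. Calcr (ENSMUSG00000023964, chromosome 6, 3685680 to 3764714, GRCm38) had a log2 fold change of 4.43 (SE 0.43, edgeR adjusted p = 6.3e-06). Further rises by the naming rule were those of Csrp3, a muscle LIM protein (2.82), Nod2, an intracellular sensor of bacterial cell wall (2.71), Hspa2, a heat shock protein of the 70 kDa family (2.71), and Ly75, an endocytic receptor of dendritic cells (2.68). Rnf43, a ubiquitin ligase that removes Wnt receptors, Elk3, an ETS transcription factor, and Prok1, a secreted prokineticin, rose by 2.5, 2.46 and 2.41 on the log2 scale. Also named were Adam1b (2.59) and H2-K1 (2.58), members of gene families whose reads can be shared, and Pate2 (2.57), so their values are uncertain. Adam1b also lies wholly inside Tmem116 on the opposite strand, over 3338 bp, and the reads of both cannot be told apart without the strand setting of the counting. Elk3 overlaps Cdk17 by 19658 bp, Pate2 overlaps Pate4, Pate3 and Pate1 by 4849, 3090 and 2312 bp, and Prok1 overlaps A630076J17Rik by 1927 bp, each on the opposite strand, and they are uncertain for the same reason. Overlaps given in the text are of whole gene spans, introns included. Without 24M replicate 4 the lower genes numbered 129, and without 12M replicate 4 they numbered 306. Other settings moved the counts further: DESeq2 called 338 lower, quality weights 1654 higher and 1657 lower, the authors' normalized CPM 1340 and 1179, and the authors' 13 normalized libraries by edgeR 1482 and 1398. The length slope gave 1184 and 1524 and the GC slope 1242 and 1246. The length slope in those 13 libraries left 106 and 35, with 130 of the 518 called. These 4 settings were chosen after seeing the data. In those 13 libraries the 24M slopes all lie above the 3M slopes, so calls lost there cannot tell age from slope.

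Among the falls, Serinc5, a multipass membrane protein (ENSMUSG00000021703, chromosome 13, 92611138 to 92711944, GRCm38), went from 13.6 ± 1.46 to 2.58 ± 0.0534 CPM (SD, n = 4), a log2 fold change of -2.39 (SE 0.12, edgeR adjusted p = 6.2e-09). Prdm1 (ENSMUSG00000038151, chromosome 10, 44437177 to 44528501) had a log2 fold change of -2.02 (SE 0.16, adjusted p = 6.2e-07). Atp8b2, a phospholipid flippase subunit, had the deepest fall by the naming rule, from 12.9 ± 2.63 to 1.69 ± 0.283 CPM (SD, n = 4), a log2 fold change of -2.94 (SE 0.33, adjusted p = 2.8e-05). Dnaic2, an axonemal dynein chain, had a log2 fold change of -2.67, Tbc1d9 of -2.42, Spaca6, a sperm membrane protein, of -2, Sestd1 of -1.99 and Gulp1, an adaptor of engulfment, of -1.97. Nrep (-1.67), Htra1, a secreted serine protease (-1.64), Mtus1 (-1.60) and Xrra1 (-1.42) completed the 12. Htra1 overlaps Fgfr2 by 49550 bp, Xrra1 overlaps Spcs2 by 4347 bp and Tbc1d9 overlaps Gm10645 by 819 bp, each on the opposite strand.

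**Figure D2:**
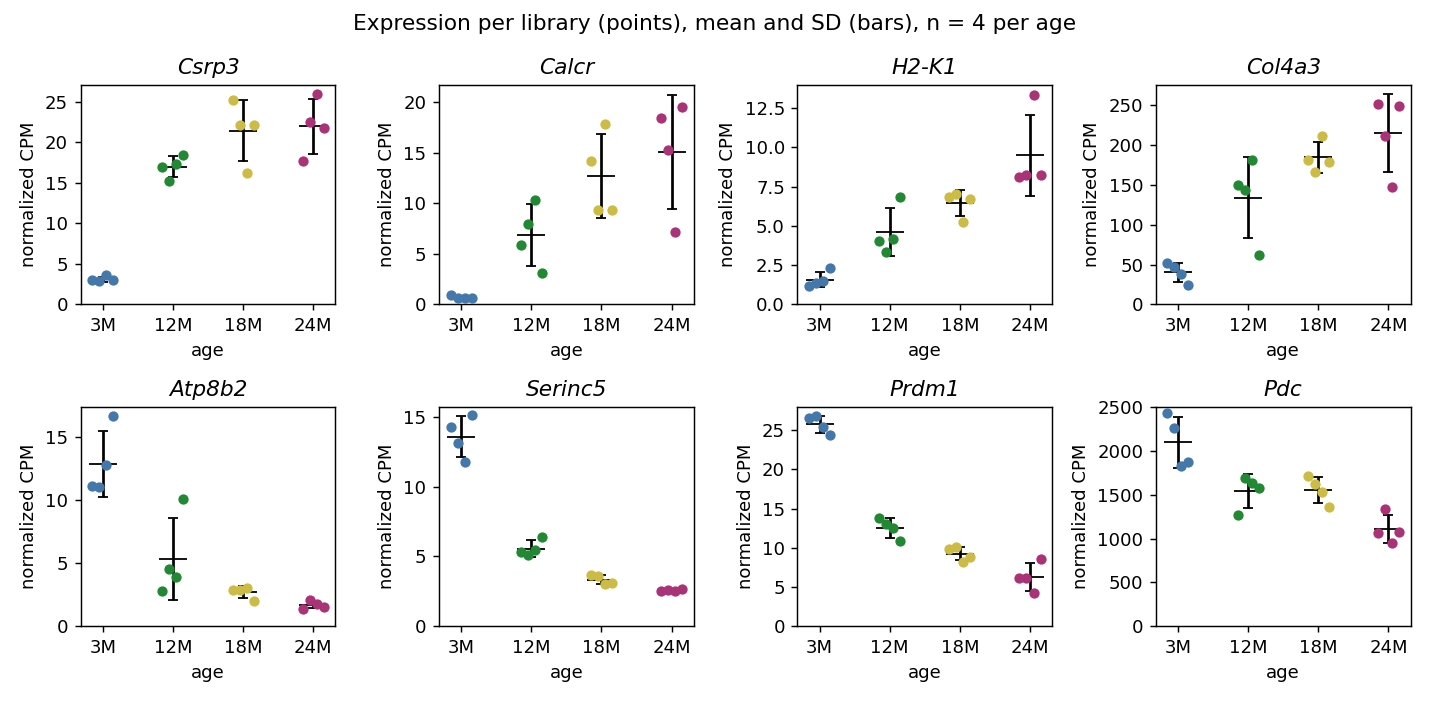
Normalized CPM of 8 genes on linear axes from 0, against age, with 1 point per library and bars for the mean and SD of 4 libraries. Csrp3, Calcr, H2-K1 and Col4a3 are higher at each later age than at 3M, and Atp8b2, Serinc5, Prdm1 and Pdc are lower in their means.

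Of the 10 tested antigen presentation genes 4 rose at 24M and none fell, also when adjusted over the list alone: Tap2, a subunit of the peptide transporter that loads class I molecules (log2 fold change 1.83), Erap1, the peptidase that trims those peptides (1.41), and the class I genes H2-K1 (2.58) and H2-Q4 (1.08), whose copies share reads. Erap1 overlaps Cast by 834 bp on the opposite strand. H2-K1 went from 1.59 ± 0.484 to 9.49 ± 2.59 CPM (SD, n = 4). The median log2 fold change of the list was 0.373 (camera adjusted p = 1.97e-07), and it was the single list of 40 called with an estimated correlation (adjusted p = 0.00283 with an estimated correlation). Of 8 tested interferon response genes only Ddx58, an RNA sensor (0.71), rose, also when adjusted over the list alone. The median of that list was 0.200 (camera adjusted p = 0.0412; adjusted p = 0.181 with an estimated correlation), and its call ended without 3M replicate 1 (0.073), 3M replicate 2 (0.068), 12M replicate 4 (0.051) or 24M replicate 3 (0.12).

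Extracellular matrix genes moved in both directions. Of 11 tested members 4 rose and 1 fell, also when adjusted over the list alone, with a median of 0.166 (camera adjusted p = 0.0149; adjusted p = 0.181 with an estimated correlation). Col4a3 and Col4a4, neighbouring genes for basement membrane collagen chains, went from 40.4 ± 12 to 215 ± 48.4 and from 41.1 ± 5.35 to 124 ± 13.4 CPM (SD, n = 4), with log2 fold changes of 2.41 and 1.59. Lamc1, a laminin chain (0.75), and Itgav, an integrin subunit (0.92), rose as well. Mmp2, a matrix metalloprotease, fell by 0.77 on the log2 scale. Of 24 lipid synthesis genes 4 rose, also when adjusted over the list alone, where Dhcr7 fell too, a name chosen after its values were seen: Scd1 and Scd2, which desaturate fatty acids (2.94 and 0.38), Abca1, a cholesterol exporter (1.28), and Cyp51, an enzyme of cholesterol synthesis (0.32). Scd1 went from 1.17 ± 0.194 to 8.96 ± 0.987 CPM (SD, n = 4), a 7.67-fold rise. The lipid list had a median of -0.002 and did not pass the test (camera adjusted p = 0.128). The call of Cyp51 ended without any 1 of 14 libraries and that of Scd2 without any 1 of 8, with an adjusted p of up to 0.16 (without 24M replicate 1 or 2) and 0.097 (without 3M replicate 2).

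Most rod genes did not pass the test. Of 24 phototransduction genes 2 fell, Pdc, which binds transducin beta-gamma, from 2100 ± 293 to 1110 ± 163 CPM (SD, n = 4; log2 fold change -0.92, edgeR adjusted p = 0.00041), and Gngt1, the rod transducin gamma subunit (-0.45, adjusted p = 0.038). Adjusted over the list alone 4 fell, adding Rcvrn (-0.42), which overlaps Glp2r by 8008 bp on the opposite strand, and Gnb1 (-0.33). The list had a median of -0.142 (camera adjusted p = 0.000232; adjusted p = 0.187 with an estimated correlation). Among 14 photoreceptor transcription factors Prdm1 and Rorb fell, also when adjusted over the list alone, with log2 fold changes of -2.02 and -0.91 (adjusted p of Rorb 0.046). The median of that list was -0.131 (camera adjusted p = 0.0324; adjusted p = 0.181 with an estimated correlation), and its call ended without 3M replicate 2 (0.051) or 3M replicate 4 (0.052). Log2 fold changes of genes that did not pass the test were -0.31 for Nrl (edgeR adjusted p = 0.33), -0.19 for Crx (0.44), 0.03 for Nr2e3 (0.96) and -0.32 for Gnat1 (0.38). Nr2e3 turned to -0.03 with quality weights and to -0.02 in the 13 libraries of the authors' normalized table. The calls of Gngt1 and Rorb ended without any 1 of 9 and 12 of the 16 libraries, with an adjusted p of up to 0.13 (without 24M replicate 4) and 0.14 (without 3M replicate 1).

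The ribosomal protein, nuclear respiratory chain, proteasome, TCA cycle, antioxidant and chaperone lists had medians below 0, with few called members. Medians were -0.260 for 67 cytosolic ribosomal proteins (camera adjusted p = 2.6e-08; adjusted p = 0.643 with an estimated correlation), -0.225 for 35 complex I subunits (1.96e-05; adjusted p = 0.643 with an estimated correlation), -0.263 for 35 subunits of complexes III to V (2.94e-08; adjusted p = 0.53 with an estimated correlation) and -0.194 for 31 proteasome subunits (4e-05; adjusted p = 0.53 with an estimated correlation). The TCA cycle list of 25 genes had a median of -0.074 (camera adjusted p = 0.0028; adjusted p = 0.441 with an estimated correlation), 22 antioxidant genes one of -0.141 (0.0122; adjusted p = 0.643 with an estimated correlation) and 20 cytosolic chaperones one of -0.151 (0.00606; adjusted p = 0.53 with an estimated correlation). Called members were, also when adjusted over the list alone, Idh3a of the TCA cycle (-0.55), cytochrome c, Cycs (-0.38), the proteasome subunit Psma4 (-0.37), the thioredoxin-like Nxnl2 (-1.07) and catalase, Cat (-0.69), and the chaperone Dnaja2 (-0.41). No member of the ribosomal or complex I list was called. These libraries also differed in transcript-length slope, with a mean of -0.047 ± 0.025 log2 units per doubling of length at 3M and 0.008 ± 0.088 at 24M (SD, n = 4), and the ribosomal and respiratory transcripts are short. With the length slope as a covariate, chosen after seeing the data, the calls of ribosomal proteins (median -0.106, adjusted p = 0.0712), complex I (-0.102, 0.0715), antioxidant genes (-0.022, 0.331), TCA cycle (-0.077, 0.2) and chaperones (-0.135, 0.1) ended, and those of complexes III to V (-0.133, 0.00893) and the proteasome (-0.096, 0.0389) did not. The medians of the TCA cycle and chaperones were -0.074 and -0.151 without the slope. The call of Cycs ended without any 1 of 11 libraries, with an adjusted p of up to 0.13 (without 3M replicate 2). That of Psma4 ended without 3M replicate 2 (0.065), 3M replicate 4 (0.067), 24M replicate 1 (0.078) or 24M replicate 4 (0.071), and that of Dnaja2 without 3M replicate 1 (0.051) or 3M replicate 2 (0.056).

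**Figure D3:**
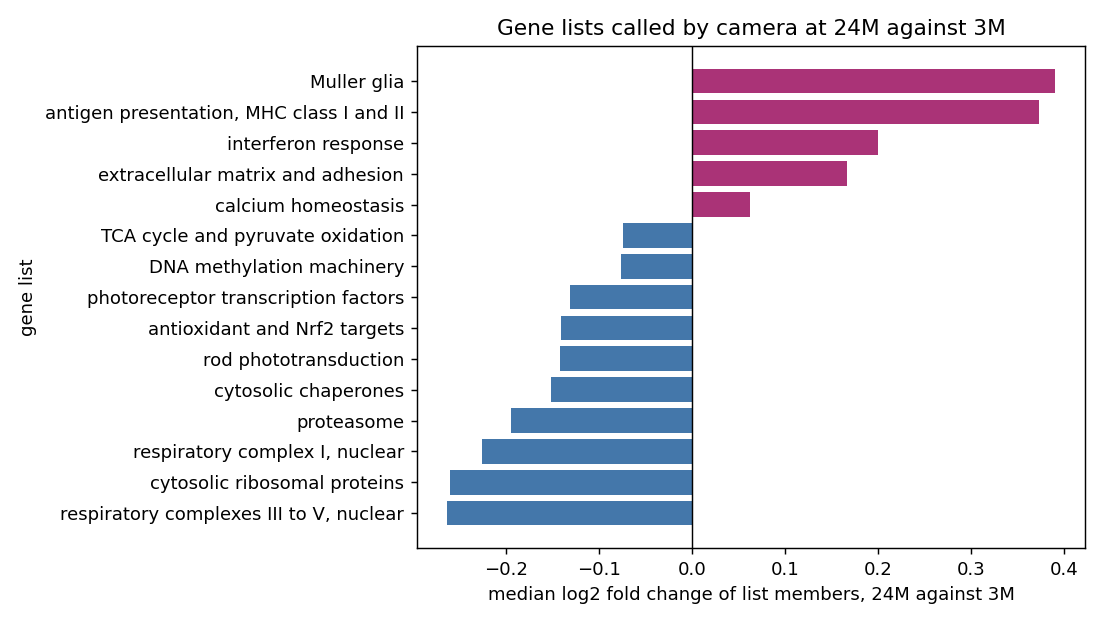
Bars give the median log2 fold change at 24M against 3M of the members of the 15 gene lists called by camera with the preset correlation, 5 above 0 and 10 below. Antigen presentation (0.373) was the one list of these also called with an estimated correlation.

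DNA methylation genes moved in both directions. Of 20 tested members 1 rose, Gadd45b, a stress-induced gene tied to demethylation (log2 fold change 1.67), and 2 fell, Gadd45a (-0.46) and Tet1, a methylcytosine oxidase (-0.50). Adjusted over the list alone 1 rose and 4 fell, adding Zbtb4 and Idh2, the latter named after its values were seen. The median was -0.076 (camera adjusted p = 0.0327; adjusted p = 0.181 with an estimated correlation), and the call ended without 3M replicate 2 (0.068), 3M replicate 4 (0.052) or 24M replicate 3 (0.086). The call of Tet1 ended without 3M replicate 3 (0.053), 24M replicate 1 (0.057) or 24M replicate 4 (0.057). Tet2 (-0.04), Tet3 (-0.16), Dnmt1 (-0.04) and Dnmt3a (-0.16) did not pass the test. Tet2 turned to 0.16 in the 13 libraries of the authors' normalized table, and Dnmt1 to 0.05 with the length slope as a covariate.

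Of 19 calcium homeostasis genes 2 rose, Itpr2, an intracellular calcium channel (0.78), and Camk2g, a calmodulin kinase (0.29), and 3 rose when adjusted over the list alone, adding Itpr1. The median was 0.062 (camera adjusted p = 0.0412; adjusted p = 0.441 with an estimated correlation), and the call ended without 3M replicate 2 (0.068), 3M replicate 3 (0.094), 3M replicate 4 (0.055), 12M replicate 4 (0.057) or 24M replicate 2 (0.2). Of 17 Müller glia markers 1 rose, Car2, a carbonic anhydrase (0.50), also when adjusted over the list alone. That list had a median of 0.390 (camera adjusted p = 0.0149; adjusted p = 0.688 with an estimated correlation), and its call ended without 3M replicate 2 (0.14), 3M replicate 3 (0.06) or 24M replicate 2 (0.079). Summed CPM of 24 Müller glia markers was 379 ± 83.9 at 3M and 484 ± 55 at 24M (SD, n = 4; exact permutation p = 0.1143, Benjamini-Hochberg 0.4889). With the length slope as a covariate the calls of the Müller glia (0.00605), rod phototransduction (0.00605) and antigen presentation lists (7.61e-05) did not end. The GC slope ended those of Müller glia (0.0548), calcium homeostasis (0.0679) and extracellular matrix (0.0786), and not that of rod phototransduction (0.000182). The length slope ended the calls of calcium homeostasis (median 0.15, adjusted p = 0.0712), extracellular matrix (0.349, 0.0698), DNA methylation (-0.149, 0.0712), transcription factors (-0.148, 0.0698) and interferon response (0.164, 0.0712), of which the first 4 medians were larger in size than without it. In the 13 libraries of the authors' normalized table these 5 calls ended as well (0.0764, 0.0704, 0.109, 0.0704 and 0.139). Glul, glutamine synthetase of Müller glia, had a log2 fold change of 0.43 (edgeR adjusted p = 0.69). Cone genes Opn1sw (-0.20, adjusted p = 0.9) and Arr3 (0.10, adjusted p = 0.95) did not pass the test, with 6.30 ± 1.54 and 11.4 ± 1.96 CPM at 24M (SD, n = 4), and turned to 0.08 with quality weights (Opn1sw) and to -0.08 without 3M replicate 2 (Arr3). Opn1mw, Gfap and C1qa lay below the expression filter, at 1.77 ± 0.548, 1.43 ± 0.63 and 0.0991 ± 0.0767 CPM at 24M, as did Xist at 1.93 ± 0.555 (SD, n = 4).

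At 12M the first of these differences were already present. Calcr (log2 fold change 3.29) and Csrp3 (2.45) were among the largest rises against 3M, and Dnaic2 (-1.97), Spaca6 (-1.54) and Serinc5 (-1.29) among the largest falls by the naming rule. Prdm1 stood at 12.6 ± 1.28 CPM (SD, n = 4; log2 fold change -1.04, edgeR adjusted p = 0.0011). In all, 119 genes were higher and 50 lower by the edgeR test, 40 and 12 of them at least 2-fold, and 1114 had an unadjusted p under 0.05. Of the 169 called genes 167 had no overlap between the libraries of each age, against 620 of all genes (5.09%), where chance gives 2.86%. Slc29a4, a monoamine transporter (2.14), Pate2 (1.99) and Dnah7c (1.96) completed the named rises, and Dnah7c belongs to a gene family whose reads can be shared. Atp8b2 (-1.28, adjusted p = 0.045) and Podxl2 (-1.16, adjusted p = 0.035) completed the named falls, but their calls ended without 14 and 10 of the 16 libraries, with an adjusted p of up to 0.19 and 0.15. Of the 10 antigen presentation genes 3 rose, also when adjusted over the list alone, Erap1 (1.14), Tap2 (1.00) and H2-K1 (1.53), with a list median of 0.158 (camera adjusted p = 0.00167; adjusted p = 0.0809 with an estimated correlation). Of 40 lists camera called 9, and none was called with an estimated correlation.

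The counts at 12M rest on single libraries more than those of the other ages. Without 12M replicate 4, higher genes numbered 273 and lower genes 260. Lower genes numbered 28 without 3M replicate 3, 32 without 3M replicate 4, and 30, 27 and 25 without 12M replicates 1, 2 and 3. In the 13 libraries of the authors' normalized table, an alternative chosen after seeing the data, 2368 genes were higher and 2284 lower, and with the length slope in these libraries 10 and 0 by edgeR (in all 16 libraries without the slope, 1114 genes had an unadjusted p under 0.05). In these 13 libraries the 12M slopes all lie above the 3M slopes, so this loss of calls cannot tell age from slope. DESeq2 called 214 higher and 99 lower, quality weights 2878 and 2949, the authors' normalized CPM 2085 and 1839, the length slope 245 and 195, the GC slope 345 and 237, and a fit of these 2 ages alone 74 and 32.

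Calcr (log2 fold change 4.18), Csrp3 (2.78), Pate2 (2.41), Hspa2 (2.40) and Nod2 (2.38) were among the largest rises at 18M against 3M. Dnaic2 (-2.33), Atp8b2 (-2.25), Serinc5 (-2.02), Spaca6 (-1.91), Tbc1d9 (-1.84) and Prdm1 (-1.48) were the largest falls by the naming rule. In all, 205 genes were higher and 117 lower by the edgeR test, 73 and 33 of them at least 2-fold, with 1510 at an unadjusted p under 0.05. Of the 322 called genes 319 had no overlap, against 1666 of all genes (13.68%), where chance gives 2.86%. Antigen presentation had 4 of 10 members higher, Tap2 (1.47), Erap1 (1.29), H2-K1 (2.03) and H2-Q4 (0.73), also when adjusted over the list alone, with a median of 0.248 (camera adjusted p = 7.74e-06; adjusted p = 0.00859 with an estimated correlation). Camera called 11 lists in all, of which this was the single one called with an estimated correlation. Without 12M replicate 4, higher genes numbered 309 and lower genes 205, and without 3M replicate 3 higher genes numbered 137. Higher and lower genes numbered 330 and 198 by DESeq2, 652 and 458 with quality weights, 380 and 216 in the authors' normalized CPM, 454 and 270 in its 13 libraries by edgeR, 516 and 384 with the length slope and 646 and 446 with the GC slope.

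Calls at 18M and 24M against 3M overlapped in 187 higher and 98 lower genes, and none was called in opposite directions. Both comparisons share the 3M libraries. Independent lists of these sizes would share 5.44 and 1.87 genes, and 20 simulations of unchanged groups against the same controls gave 0, a value that leaves out the effects and follows from the few calls such groups give. With the 3M libraries split 2 and 2, the overlap of 285 became 139 to 157 over the 6 assignments. With 2 controls per comparison the calls themselves fell too. At 18M they went from 205 higher and 117 lower to 99 to 132 and 55 to 86. At 24M they went from 323 and 195 to 167 to 223 and 91 to 132. The smaller overlap therefore cannot tell the sharing of controls from the loss of calls. The log2 fold changes of both comparisons had a correlation across genes of 0.82 against 0.51 in the simulations, and a covariance of 0.0731 against 0.0189, a difference of 0.0542. The simulated genes were drawn independently, so these simulations leave out a shift of the shared 3M libraries along the first component. The difference therefore cannot tell age from such a shift. With the 3M libraries split the correlation was 0.383 to 0.745 and the covariance 0.0472 to 0.071. Genes are not independent replicates.

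For 18M against 12M edgeR called 1 gene, Gm28876, a long intergenic noncoding RNA (ENSMUSG00000101356, chromosome 15, 103096151 to 103102111, GRCm38), named after its values were seen. It was higher at 18M with a log2 fold change of 2.04 (SE 0.23, edgeR adjusted p = 0.0019), and 271 genes had an unadjusted p under 0.05. Its summed counts were 2, 167, 666 and 1241 from 3M to 24M, and its mean CPM 0.0196 ± 0.0227, 1.80 ± 0.525, 7.37 ± 1.62 and 12.3 ± 1.93 (SD, n = 4). The ratio of its summed counts to 3M, per total count, was 91 (95% exact interval 24.8 to 758) at 12M, 382 (105 to 3160) at 18M and 643 (178 to 5320) at 24M. The call ended in a fit of these 2 ages alone, which called 0 higher. No gene was lower at 18M than at 12M by edgeR, and 1 was lower without 24M replicate 1. Higher and lower genes numbered 8 and 4 by DESeq2, 1513 and 827 with quality weights, 183 and 50 in the authors' normalized CPM, 174 and 52 in its 13 libraries by edgeR, 10 and 7 with the length slope and 10 and 8 with the GC slope. Antigen presentation was called between these ages as well, with a median of 0.190 (camera adjusted p = 4.01e-05; adjusted p = 0.0103 with an estimated correlation), although none of its 10 members was called over all genes and 2, Tap2 (0.47) and H2-Q4 (0.43), rose when adjusted over the list alone. For 24M against 18M edgeR called 0 genes in either direction, with 680 at an unadjusted p under 0.05 and a smallest adjusted p of 0.053, while DESeq2 called 17 higher and 18 lower, voom called 1 higher, and leaving out 12M replicate 4 gave 1 higher. Higher and lower genes there numbered 218 and 362 with quality weights, 8 and 12 in the authors' normalized CPM, 3 and 9 in its 13 libraries, 91 and 80 with the length slope and 74 and 78 with the GC slope. The lysosome list of 30 genes was called lower at 18M than at 3M (median -0.126, camera adjusted p = 0.0119; adjusted p = 0.62 with an estimated correlation) and than at 12M (-0.076, 0.00102; adjusted p = 0.796 with an estimated correlation). It was called higher at 24M than at 18M (median 0.110, camera adjusted p = 0.00476; adjusted p = 0.99 with an estimated correlation), with no member called over all genes or when adjusted over the list alone.

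Over the 4 ages as a linear term in months, 346 genes rose and 238 fell by the edgeR test, with 1782 at an unadjusted p under 0.05. Tmem116, a membrane protein, rose by 0.0906 log2 units per month, and Serinc5 and Tbc1d9 had slopes of -0.118, each with an adjusted p of 3.4e-09. Other rising genes named by the smallest p were Prok1 (0.112), Rnf43 (0.118), Tap2 (0.0866), Zbtb8a, a zinc finger protein (0.083), and Fndc1, a fibronectin domain protein (0.0698 log2 units per month). Gulp1 (-0.0942), Prdm1 (-0.0957), Sestd1 (-0.0956) and Mtus1 (-0.0754) were the other falling ones. Tmem116 overlaps Adam1a and Adam1b, and Zbtb8a overlaps Zbtb8os by 920 bp, on the opposite strand. Without 3M replicates 1, 2 or 4 the falling genes numbered 149, 145 and 158, and without 24M replicate 3 they numbered 369. The F-test of any difference among the 4 ages called 344 genes, with 1311 at an unadjusted p under 0.05, and gave 221 without 3M replicate 2 and 543 without 12M replicate 4. Rising and falling genes numbered 1202 and 1186 with quality weights, 536 and 361 in the authors' normalized CPM, 585 and 471 in its 13 libraries, 1106 and 1301 with the length slope and 1170 and 1078 with the GC slope. In these settings the F-test called 5434, 3082, 3545, 1668 and 1749 genes, and DESeq2 called 665.

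The authors' deposited table of comparisons lists 11826 genes, of which 3156 have an adjusted p under 0.05 there. Of 333 genes called by the F-test of edgeR and listed in the authors' deposited table, 319 are under 0.05 in it. The authors' deposited table gives Prdm1 log2 differences from 3M of -1.11, -1.45 and -1.98 at 12M, 18M and 24M, and Gm28876 differences of 5.52, 7.62 and 8.45.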

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

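In this part the tests of Müller glia and microglia RNA, the library-level tests of the matched lists, and the counts over other splits of the libraries were chosen after the results were seen, as were the alternatives with 13 libraries and with the slope covariates.

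A single library lay far from the other 3 of its age in 42 of 440 groups of values tested, where chance gives about 1 in 20. Of these values 23 belong to 12M replicate 4, 7 to 24M replicate 3 and 4 to 18M replicate 3, the libraries that are not in the authors' normalized table. 12M replicate 4 stood at 40.76 on the first principal component against -25.98 to -18.47 in the others, and at -3.42 on the second against 2.30 to 2.96. Its transcript-length slope was -0.1335 against 0.0649 to 0.0745 and its GC slope 0.3765 against -0.2479 to -0.2062. 24M replicate 3 stood at -20.74 on the second component against -11.84 to -10.67.

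Marker sums set 12M replicate 4 apart as well, with 38.24 CPM of T cell and B cell markers against 67.59 to 70.79, 619.1 of endothelial cell and pericyte markers against 398.5 to 410.4, and 111.2 of retinal pigment epithelium markers against 73.94 to 79.51. The rod genes Gnat1 and Rcvrn were high in it, at 5564 CPM against 3727 to 4040 and 581.2 against 448 to 459.6. It was also high for Ldhb (35.67 CPM), Nxnl2 (63.71), Psma4 (50.8), Shmt2 (24.47), Irs1 (25.42), Car2 (114.6), Htra1 (21.54), Podxl2 (13.62), Slc29a4 (25.83) and Tbc1d9 (10.04). It was low for Tet2 (149.1 CPM against 257.2 to 275.4), Tet3 (415.8), Dnmt3a (215.1) and Dnah7c (18.16 against 52.48 to 53.01).

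24M replicate 3 was low for Rorb (147 CPM against 271.2 to 289.1), Dnah7c (20.44) and the sum of microglia and macrophage markers (44.53 against 52.23 to 53), and high for H2-K1 (13.36 CPM against 8.123 to 8.234), Nxnl2 (37.42) and Rnf43 (31.72). 18M replicate 3 was high for Tet2 (285.8 CPM against 219.3 to 220.9), Col4a4 (133.5) and Decr1 (3.211), and low for Sept4 (25.56). The other single values were Atp8b2 at 1.975 and Camk2g at 110.8 CPM in 18M replicate 4, Bcl2l11 at 55.32 in 18M replicate 2, Calcr at 0.9116 in 3M replicate 1, Irs1 at 16.08 in 3M replicate 4, Tet1 at 8.187 in 3M replicate 3, Elk3 at 9.016 in 24M replicate 4 and Tmem116 at 29.54 in 24M replicate 2.

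At 12M against 3M 4652 genes were called in the 13 libraries of the authors' normalized table, against 169 in all 16. A candidate explanation is the length and GC axis of the libraries, since without 12M replicate 4 the 12M slopes (mean 0.0683) lie apart from those of 3M (mean -0.0468). Slope coefficients fitted within the 18M and 24M libraries gave the sign of 96.6% of these calls, and of 86.7% of all genes tested. With the slope as a covariate the median absolute log2 fold change of these genes went from 0.378 to 0.133, and 10 of them were called in the 13 libraries and 316 in the 16. In the 13 libraries every 12M slope (0.0649 to 0.0745) lies above every 3M slope (-0.0811 to -0.0257). The covariate there largely stands in for age, so this drop cannot tell age from slope. Age as the source of the slope difference itself was not tested and stays open.

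The ribosomal, respiratory and proteasome lists were called lower at 24M than at 3M with the preset correlation, but not with an estimated one (adjusted p = 0.643 for ribosomal proteins and complex I and 0.53 for complexes III to V and the proteasome, each with an estimated correlation), and short transcripts as a class may account for part of that. Among 10000 random lists matched on length and expression the percentile of the median was 0 for ribosomal proteins, 0.09 for complex I, 0.01 for complexes III to V and 0.01 for the proteasome, and among lists matched on response to the length slope it was 0 for each of the 4. The length-matched lists fell too, with medians of -0.124, -0.112, -0.118 and -0.065 in this order, against -0.260, -0.225, -0.263 and -0.194 for the lists themselves. Slope-matched lists had medians of -0.072, -0.037, -0.035 and -0.028. Over libraries, list minus length-matched genes differed at 24M from 3M by -0.138 for complex I (exact permutation test, p = 0.0286). The difference was -0.183 for complexes III to V (exact permutation test, p = 0.0286). It was -0.182 for ribosomal proteins (exact permutation test, p = 0.1143) and -0.138 for the proteasome (exact permutation test, p = 0.0571). Against slope-matched genes the exact permutation p was 0.0286 for both respiratory lists and the proteasome and 0.0857 for ribosomal proteins. These exact permutation p-values were not adjusted over the lists, and 0.0286 is the smallest that 4 libraries against 4 allow. The tests therefore cannot decide on length alone for any of the 4 lists. The percentiles cannot decide it either, because random lists ignore that members move together. With the slope as a covariate in the fit, medians shrank from -0.260 to -0.106 for ribosomal proteins, -0.225 to -0.102 for complex I, -0.263 to -0.133 for complexes III to V and -0.194 to -0.096 for the proteasome, and the first 2 calls ended as the medians shrank (adjusted p = 0.0712 and 0.0715), so the pattern is not kept whole. GC content was not matched, and age stays open as untested.

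RNA of other cells that pass the sort on green fluorescent protein (purity above 98% per the labels) could raise genes at 24M, and 105 genes were at least 2-fold higher at 24M, with a median log2 fold change of 1.46. The Müller glia markers had a median of 0.39 and an upper quartile of 0.49, below the rise of 1 that the smallest member of the pattern would need, and the highest was Rlbp1 at 0.79. Of the microglial transcripts C1qa, C1qb and C1qc the highest value in a 24M library was 0.241 CPM, against a median rise of 11.8 CPM in the pattern, although the microglial gene Siglech rose (0.69, edgeR adjusted p = 0.023). Microglial RNA is therefore argued against for the pattern as a set, and so is a 2-fold larger share of Müller glia RNA, as far as these markers measure it. The marker test cannot cover genes induced within Müller glia, whose summed markers stood at 379 ± 83.9 CPM at 3M and 484 ± 55 at 24M (SD, n = 4). Other cell types and the sort itself were not tested in this way. That rods themselves change with age is a hypothesis that stays open, found and tested on the same data.

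Other splits of the same libraries into groups of the same sizes gave as many genes as the real ages in few cases. For 12M against 3M the real split called 169 genes and the highest of the others 1, for 18M 322 and 0, and for 24M 518 and 2, in each case 1 of 35 splits, which argues against chance. For 18M against 12M, 2 of 35 splits reached the real count of 1, with 1 as the highest other, so chance is not excluded. For 24M against 18M the real count was 0, which 35 of 35 splits reach in any case, so this count says nothing about chance, with 2 as the highest other. For any difference among the 4 ages 2 of 60 splits reached the real count of 344, but another split called 3967 genes, which points to a structure of the samples. For the linear term 1 of 60 splits reached the real count of 584, with 48 as the highest other, which argues against chance.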

How the results depend on the processing

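The 13 libraries, the length slope, the GC slope and the 13 libraries with the length slope are alternatives chosen after seeing the data. In the 13 libraries the length slopes of the later ages all lie above those of 3M. Calls lost there with the slope therefore cannot tell age from slope. Of 104 named results that were called, 85 lost no call when 1 library was left out, 79 were called in every planned setting, 104 with the 13 libraries, 104 with the length slope and 58 with that slope in 13 libraries. Most named genes were picked from these same data by fold change or p, which favours stable calls. Over all genes, 371 of 518 calls at 24M remained without 3M replicate 2, and 108 of 169 at 12M without 12M replicate 3. For the named genes and the called lists over all alternatives, 3613 values stayed on their side of the threshold, 303 became weaker, 40 stronger and 19 reversed. The counts of called genes and of called lists and the overlap are not among these values. Of the 518 genes called at 24M against 3M, 518 were also called by DESeq2, in the 13 libraries and with either slope, and 130 with the length slope in 13 libraries. Causes below were not tested except where fewer libraries or genes entered. Counts that moved by over 1.5 times follow as higher and lower.

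DESeq2 gave 214 and 99 at 12M, 330 and 198 at 18M, 338 lower at 24M against 3M, 8 and 4 for 18M against 12M, 17 and 18 for 24M against 18M, and 665 by the test of 4 ages. Voom gave 1 higher at 24M against 18M. Quality weights gave 2878 and 2949, 652 and 458, 1654 and 1657 against 3M, 1513 and 827 for 18M against 12M, 218 and 362 for 24M against 18M, 5434 among 4 ages, and 1202 rising and 1186 falling. The authors' CPM with pseudocount 0.5 gave 2085 and 1839, 380 and 216, 1340 and 1179 against 3M, 183 and 50, 8 and 12 between later ages, 3082 among ages, and 536 rising and 361 falling. With pseudocount 2 these were 2096 and 1848, 383 and 222, 1354 and 1186, 200 and 61, 9 and 12, 3102, and 535 and 369. Fits of the compared ages alone gave 74 and 32 at 12M, 202 lower at 18M, and 0 higher at 18M against 12M. A minimum of 1 CPM gave 187 lower at 18M.

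The 13 libraries gave 2368 and 2284, 454 and 270, 1482 and 1398 against 3M, 174 and 52, 3 and 9 between later ages, 3545 among ages, and 585 and 471 for the linear term. The length slope gave 245 and 195, 516 and 384, 1184 and 1524, 10 and 7, 91 and 80, 1668, and 1106 and 1301. The GC slope gave 345 and 237, 646 and 446, 1242 and 1246, 10 and 8, 74 and 78, 1749, and 1170 and 1078. The length slope in 13 libraries gave 10 and 0 at 12M, and 106 and 35 at 24M. Lists called at 24M numbered 15, 1 with an estimated correlation, 7 by fry, 8 with the length slope and 9 with it in 13 libraries. The overlap of 18M and 24M calls was 658 in the 13 libraries, 754 with the length slope, 891 with the GC slope, 137 with the length slope in 13 libraries, and 139, 140, 142, 157, 144 and 145 with split controls.

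Leaving out each library gave ranges of 83 to 273 higher and 25 to 260 lower at 12M, 137 to 309 and 79 to 205 at 18M, and 244 to 419 and 129 to 306 at 24M. Ranges were 1 to 1 higher and 0 to 1 lower for 18M against 12M, 0 to 1 higher and 0 to 0 lower for 24M against 18M, 221 to 543 among ages, 237 to 477 rising, 145 to 369 falling, 10 to 18 lists and 204 to 400 in the overlap. For log2 fold changes at 24M they were -0.02 to 0.10 for Nr2e3, -0.17 to 0.16 for Tet2, -0.11 to 0.02 for Dnmt1, -0.36 to 0.19 for Opn1sw and -0.08 to 0.45 for Arr3.

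Reversed log2 fold changes at 24M, none of them called, were Nr2e3 -0.03 (quality weights), -0.01 (without 3M replicate 1), -0.02 (without 24M replicate 3) and -0.02 (13 libraries), and Tet2 0.12 (quality weights), 0.06 and 0.06 (authors' CPM), 0.16 (without 24M replicate 3) and 0.16 (13 libraries). Dnmt1 turned to 0.02 (without 3M replicate 4), 0.01 (without 24M replicate 1), 0.05 (length slope) and 0.26 (the slope in 13 libraries), Opn1sw to 0.08 (quality weights), 0.19 (without 3M replicate 1), 0.05 (length slope) and 0 (the slope in 13 libraries), and Arr3 to -0.08 and -0.06 (without 3M replicates 2 and 3).

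Replicate numbers did not pair the libraries: 11 of 24 same-numbered pairs had a correlation of deviations above 0.1 (median 0.06, -0.744 to 0.726; -0.065 for other pairs), and 0 libraries correlated best with their own number at every other age. The replicate block gave 99 and 37, 171 and 98, 285 and 159 calls against 3M, 1 and 0, 0 and 0 between later ages, 266 among ages, 298 and 195 for the linear term, and 16 lists. With the block the complement list at 24M was called as well (adjusted p = 0.0471), which it was not without it (0.0561). In counts simulated at this depth with 4 libraries per age, edgeR called 30 of 50 genes changed 1.5-fold; depth was not varied, so its share in the missed ones was not tested.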

Other observations

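In this part the genes outside the naming rule (Edn2, Stat3, Sept4 and Siglech) were chosen after their values were seen. Each test is the edgeR or camera test of 24M against 3M, except the exact permutation test of summed astrocyte markers. Fuel metabolism moved in single genes. Decr1, a reductase of unsaturated fatty acid oxidation, fell from 7.26 ± 0.861 to 2.21 ± 0.167 CPM (SD, n = 4; log2 fold change -1.72, edgeR adjusted p = 4.3e-05), and Acadm, a dehydrogenase of medium-chain fatty acids, rose by 0.40 (0.025), among 24 tested genes of fatty acid oxidation (median 0.020, camera adjusted p = 0.649). Shmt2, a mitochondrial enzyme of one-carbon metabolism, fell by 1.03 (adjusted p = 0.0023), and the list of 16 had a median of -0.038 (0.391). Ldhb, a lactate dehydrogenase subunit, rose by 0.68 (0.03) among 23 glycolysis genes (median -0.140, 0.114). Irs1, an adaptor of the insulin receptor that overlaps Gm9747 by 2822 bp on the opposite strand, rose from 9.16 ± 4.64 to 24.8 ± 1.79 CPM (SD, n = 4; log2 fold change 1.44, adjusted p = 0.0015), with 28 genes of mTOR and insulin signalling at a median of 0.037 (0.46). The call of Acadm ended without any 1 of 6 libraries, with an adjusted p of up to 0.084 (without 3M replicate 4), and that of Ldhb without any 1 of 6, with up to 0.11 (without 3M replicate 2).

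Stress and turnover lists held few called genes. Asns, asparagine synthetase, and Ern1, a sensor of unfolded proteins, rose by 0.55 (edgeR adjusted p = 0.023) and 0.32 (0.012) among 25 genes of the unfolded protein response (median -0.114, camera adjusted p = 0.214). Park2, a ubiquitin ligase of mitophagy, rose by 0.60 (0.0014), Npc1, a lysosomal cholesterol transporter, by 0.44 (0.00058), the base excision repair glycosylase Neil2 by 0.63 (0.0062) and the proapoptotic gene Bcl2l11 by 0.48 (0.00026). Npc1 overlaps Rmc1 by 967 bp on the opposite strand. Of 19 clock genes Hlf rose by 0.57 (0.013), and Csnk1e (-0.40, 0.02) and Rorb (-0.91, 0.046) fell. Gnb3, the cone transducin beta subunit, rose from 16.3 ± 1.34 to 31.9 ± 7.63 CPM (SD, n = 4; log2 fold change 0.97, adjusted p = 0.0023), the neurofilament gene Nefh by 0.62 (0.0026), and Tubb3, a neuronal tubulin that overlaps Gm20388 by 10592 bp on the same strand, fell by 0.76 (0.02). Edn2, an endothelin of injured photoreceptors, went from 2.54 ± 1.01 to 9.37 ± 4.01 CPM (SD, n = 4; log2 fold change 1.87, adjusted p = 0.00073), and Stat3 rose by 0.38 (0.006). Sept4 (-0.57, 0.02) fell and Siglech (0.69, 0.023) rose. Calls ended without any 1 of 4 libraries for Asns (adjusted p up to 0.084, without 3M replicate 4), 2 for Ern1 (0.052, without 3M replicate 2), 2 for Hlf (0.057, without 3M replicate 2), 3 for Csnk1e (0.076, without 24M replicate 4), 12 for Rorb (0.14, without 3M replicate 1), 4 for Tubb3 (0.079, without 24M replicate 4), 5 for Sept4 (0.08, without 24M replicate 1) and 5 for Siglech (0.096, without 24M replicate 1).

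Other lists did not pass the camera test at 24M against 3M in the fit of 16 libraries without covariates. Alternatives chosen after seeing the data called some of them or of those above: outer segment and cilium transport with the length slope (adjusted p = 0.0101) and the GC slope (0.0199), immediate early genes (0.00957) and lipid synthesis (0.0169) with the length slope, and glycolysis in the 13 libraries of the authors' normalized table (0.000912). Medians were -0.063 for 40 genes of outer segment and cilium transport (camera adjusted p = 0.0706), -0.129 for 11 of the visual cycle (0.26), 0.010 for 28 of the ribbon synapse (0.589), 0.069 for 13 mitochondrially encoded genes (0.5), 0.043 for 34 of autophagy (0.649), -0.002 for 30 of the lysosome (0.884) and -0.020 for 30 of mitochondrial dynamics (0.46). They were -0.004 for the clock (0.589), 0.023 for 54 histone modifiers (0.875), 0.006 for 34 DNA repair genes (0.999), -0.046 for 20 cell death genes (0.906), 0.292 for 6 complement genes (0.0561), 0.025 for 14 immediate early genes (0.373) and -0.051 for 35 splicing factors (0.12). Cell type lists had medians of 0.088 for 9 cone genes (0.12), 0.127 for 9 bipolar (0.649), 0.186 for 8 amacrine (0.669), 0.25 for 5 ganglion cell (0.46) and 0.021 for 5 pigment epithelium genes (0.999). Senescence, astrocyte, endothelial and pericyte, and T cell and B cell lists had 4 tested genes each, sex-linked genes 4, red blood cells 1 and lens and cornea 0, with none called. Of the other lists too small to test, neuronal stress and gliosis had 2 of 4 tested genes higher (Edn2 and Stat3), microglia and macrophage 1 of 4 higher (Siglech) and horizontal cells 1 of 2 lower (Sept4). Summed CPM of 9 astrocyte markers was 444 ± 17.2 at 3M and 362 ± 29.1 at 24M (SD, n = 4; exact permutation p = 0.0286, Benjamini-Hochberg 0.4004).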
